A study of Mus musculus with 3 samples.

How the data were processed

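The series describes immune cells from metastasis-bearing mouse brains, measured as transcripts (10x Genomics single cell 3' v3 chemistry), antibody tags and hashtags of the same pooled cells. The 3 deposited samples are these 3 libraries of 1 capture and not 3 biological samples. Per the labels' protocols, brains were perfused and digested, and immune cells were enriched by Percoll gradient centrifugation. The deposited values are raw counts of UMIs per feature and barcode, made with Cell Ranger 3.1 on build mm10 per the submitters' processing notes, which also name Seurat 3.1.1. Per the file headers the matrix holds whole-number counts for called barcodes only, over 31111 features, of which 31062 are genes or transgenes, 35 antibodies, 8 mouse hashtags and 6 human hashtags. The gene annotation behind the counts is not given in the sources used here. Per the labels, 8 samples were hashed, and no source used here ties a hashtag to a treatment, so the planned comparison of treated with untreated brains was not run. The sources also do not say whether each hashtag was a separate animal, so p-values measure only the spread between hashtag samples. All samples shared 1 capture, so no capture batch separates them. Free RNA from lysed cells may add UMIs to any barcode, and its amount was not measured, since the matrix holds called barcodes only.

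Barcodes with at least 500 genes and at most 15% mitochondrial UMIs were kept (12334 of 12908). Hashtags were called with HTODemux in Seurat 5.3.0 on centred log ratios (quantile 0.99), which gave 9896 singlets, 1712 doublets and 726 negatives. Hashtag doublets and negatives were left out of every comparison, but stayed in the barcode totals of clusters and in the counts of transgenes and human hashtags. Scrublet (in scanpy 1.11.5 with scikit-image 0.26.0, expected rate 0.1) marked 25.2% of hashtag doublets and 1.29% of singlets and served as an alternative. Counts were scaled to 10000 per barcode, logged, reduced to 3000 variable genes and 30 principal components, and clustered by Leiden on 20 neighbours at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0). Of 28 clusters, 13 were named. The same steps run under other floating-point and thread settings gave another partition, which was analysed first. In it the large macrophage cluster, here cluster 1, took the monocyte/macrophage-like name. The doublet limit below, the added alternatives and the tests of explanations were chosen after that partition had been seen. The partition reported here is the one that repeats exactly under fixed settings. Clusters were drawn again with 10 other Leiden seeds.

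A cluster took the name of the fixed marker list with the highest mean log2 fold of its summed CPM over the lower quartile of all clusters, with 10 CPM added to both. It stayed unnamed with fewer than 3 markers detected in 10% of its cells, with more markers of another list than of its own among its top 10 genes by fold, with low UMIs and no own marker there, or with over 35% hashtag doublets. The doublet limit was set after the clusters had been seen and left 3 clusters unnamed. Clusters 14 (359 barcodes) and 17 (228) scored highest for monocyte/macrophage markers and cluster 19 (129) for T cell markers, with 73.8, 42.5 and 79.8% hashtag doublets. The microglia-like class is cluster 11 (623 barcodes), with Cx3cr1, C1qc, Fcrls, P2ry12, C1qa, Cd81, Il1a, Siglech and C1qb among its leading genes. Some items are not reported here. The monocyte/macrophage-like class is cluster 9 (659 barcodes), led by Chil3, Thbs1, Hp, Lyz2, Cxcl2, Il1b, Plac8, Cxcl10, Slpi and Clec4e. Cluster 1 held 10 detected monocyte/macrophage markers and stayed unnamed, since 1 border-associated macrophage marker, Ms4a7, and 0 of its own stood in its top 10. Values with it added or in place of the named class were an alternative. Of microglia-like barcodes, 14.9% were hashtag doublets and 11.1% hashtag negatives. At doubled resolution the microglia-like name went to a cluster of 341 barcodes and another of 274. Their medians were 6562 and 20160 UMIs, with 3.81 and 26.6% hashtag doublets and 6 and 1 microglia markers in the top 10. The second scored 4.68 for microglia and 4.135 for monocyte/macrophage markers. The myeloid comparison did not separate these clusters.

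Raw counts were summed per hashtag sample and class where at least 20 cells were present. Classes were compared with the edgeR 4.0.16 quasi-likelihood test (TMM, filterByExpr) in R 4.3.3, with the hashtag sample as a block and Benjamini-Hochberg adjustment at 0.05. Both classes of a pair come from the same hashtag sample. Their deviations from the class means correlated at 0.055, 0.016, 0.19, -0.00056 and 0.21 for samples 3, 5, 6, 7 and 8 in the myeloid comparison, and at 0.022, -0.014, 0.072 and -0.17 for samples 5, 6, 7 and 8 in the T cell comparison. Marker genes were left out of the counts of passing genes in the myeloid comparison. In the T cell comparison only Cd4, Cd8a and Cd8b1 were left out, so its counts include other cell type markers. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. The estimated correlation kept the cytotoxicity and chemokine calls between the T cell sides and, of the 12 lists between the myeloid classes, the cell cycle call alone. The estimates behind these calls were 0.036, -0.21 and -0.025 in that order. Antibody tags were compared as log2 ratios of shares of all tags (0.5 added) by an exact sign-flip permutation test, for the 32 antibodies with at least 1000 counts. CD335, CXCR4 and KLRG1 had 8, 2 and 3 counts and were left out. T cell-like and regulatory T cell-like cells were split by a mixture of 2 Gaussians on the log2 ratio of CD8a to CD4 tags at a posterior over 0.9. Shares with a UMI were taken after thinning cells to 2000 UMIs. Intervals of shares are 95% Clopper-Pearson intervals. A gene with no UMI in a class is given as a bound against 3 counts over the class, and a gene with 1 to 3 UMIs as a ratio with an exact interval. Intervals and bounds cover counting error only.

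Before the data were examined, the tests, the 25 marker lists, the 12 gene lists and the rule for named genes were fixed. The lists are myeloid checkpoint and suppression, T cell checkpoint and exhaustion, interferon-stimulated, chemokines, antigen presentation, disease-associated microglia, further homeostatic microglia, cytotoxicity, glycolysis and hypoxia, dissociation and immediate early, cell cycle, and inflammatory cytokines. The rule named Cxcl10, Vsir and Cd274, the 2 members of each list with the largest passing change in 1 direction in every sample, and the 5 largest passing changes each way with at least 20 CPM outside all lists. Tnfrsf4, Prf1 and Gzma are list members that are markers as well. Other members named as examples were chosen after their values were seen. The 3 series genes were matched by symbol to the reference table for coordinates.

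The tests were run on simulated counts with 200 changed genes. For the myeloid comparison (7324 genes) 89% of 2-fold and 100% of 4-fold changes were recovered with 11 unchanged genes called. For the T cell comparison (5514 genes) the shares were 77% and 100% with 6 unchanged genes called. The antibody test was simulated over 7 samples only, which says nothing of its recovery over the 5 samples compared, where no antibody can pass. Alternatives covered DESeq2 1.42.0 size factors and Wald test, no filter on low counts, no block, 10 or 50 cells per sum, stricter cells (1000 genes, 10% mitochondrial), a hashtag margin rule (top hashtag at least 70% of counts), Scrublet doublets, leaving out each sample, clusters without list genes, antibody tag clusters, doubled resolution, T cell sides by RNA, the centred log ratio, and unthinned shares. Antibody tag clusters were named from the same RNA marker lists, and their classes hold partly other cells than the main ones. Alternatives added later are named with their effects in the closing part. Values were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots in matplotlib 3.10.9.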

Results

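Immune-enriched cell suspensions were prepared from the brains of female C57Bl/6 mice bearing metastases of E0771, a mouse mammary carcinoma line delivered through the carotid artery. They were profiled by CITE-seq, which counts transcripts and oligonucleotide-tagged antibodies in the same single cells. Some mice had received antibodies against VISTA and PD-L1, a pair of immune checkpoint proteins, and others had not. The 8 brain samples were each stained with 35 antibodies, marked with a hashtag antibody of their own and pooled in 1 capture. The treatment of each hashtag sample is not identified here. The 8 samples therefore mix treated and untreated brains, no treated group was compared with an untreated one, and cell classes were compared within each sample instead.

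The capture held 12908 barcodes with 642058717 UMIs (unique transcript molecules), 36086641 antibody tags and 8668041 hashtag counts. The median barcode held 25352 UMIs (quartiles 7128.5 and 84371.75), 4651.5 genes and 1659 antibody tags. Quality filters and hashtag calling left 9896 singlet barcodes. Hashtag samples 1 to 8 held 100, 847, 1194, 497, 2316, 2086, 1135 and 1721 singlets. Their UMI totals were 4898693, 48667386, 70490174, 31551260, 90997185, 125193153, 37725629 and 66086426. The median singlet held 47059.5 to 67341 UMIs in samples 1, 2, 3, 4 and 6 and 11244.5 to 12058 UMIs in samples 5, 7 and 8.

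Cluster 1, led by Ms4a7, Apoe and MHC class II genes, which macrophages express, held the largest share of singlets outside the high-RNA clusters, at a median of 11.1% (6.64 to 18.2% over the 8 hashtag samples). It held 1411 barcodes and carried monocyte/macrophage markers, but 1 border-associated macrophage marker and none of those stood among its top 10 genes. It was therefore left without a name and is reported by number. Among named classes, endothelial-like cells had a median of 5.96% (1.98 to 9%), monocyte/macrophage-like cells 5.68% (1 to 9.36%), T cell-like cells 4.83% (1.41 to 15.05%), microglia-like cells 4.48% (1.42 to 9%) and NK cell-like cells 3.86% (1.25 to 8.02%). Regulatory T cell-like cells had a median of 1.28%, neutrophil-like cells 0.756% and mature dendritic cell-like cells 0.650%. T cell-like cells ranged from 1.41% in sample 4 (95% Clopper-Pearson interval 0.57 to 2.88%) to 15.05% in sample 8 (13.4 to 16.8%). Shares were also taken among the named immune classes and cluster 1 alone, which leaves out the immune cells of other unnamed clusters. There cluster 1 made up 22.0 to 44.7%, monocyte/macrophage-like cells 3.70 to 24.9%, T cell-like cells 8.19 to 25.3% and microglia-like cells 4.27 to 33.3%. Sample 1, with only 27 such cells, set the 3.70 and 33.3% ends (1 and 9 cells). Without it these classes ranged from 8.97 to 24.9% and from 4.27 to 23.0%.

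A further 7 clusters, called high-RNA here, held 5407 barcodes with cluster medians of 63030 to 108100 UMIs. They carried Krt8, an epithelial keratin, at a median of 376 CPM (counts of a gene scaled to the library total) outside cluster 13, against 13.01 CPM in monocyte/macrophage-like cells. Fewer than 3 of the 6 fixed carcinoma markers were detected in each of these clusters, so they were left without a cell type name. High-RNA barcodes made up 27.8% of the singlets of sample 8 (95% interval 25.7 to 30.0%) and 71.6% of those of sample 4 (67.4 to 75.6%), with a median of 53.6%. Other clusters with no name held another 3.62 to 10.7% of singlets. No test was run on these shares, which were measured after immune cells had been enriched on a density gradient.

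**Figure D1:**
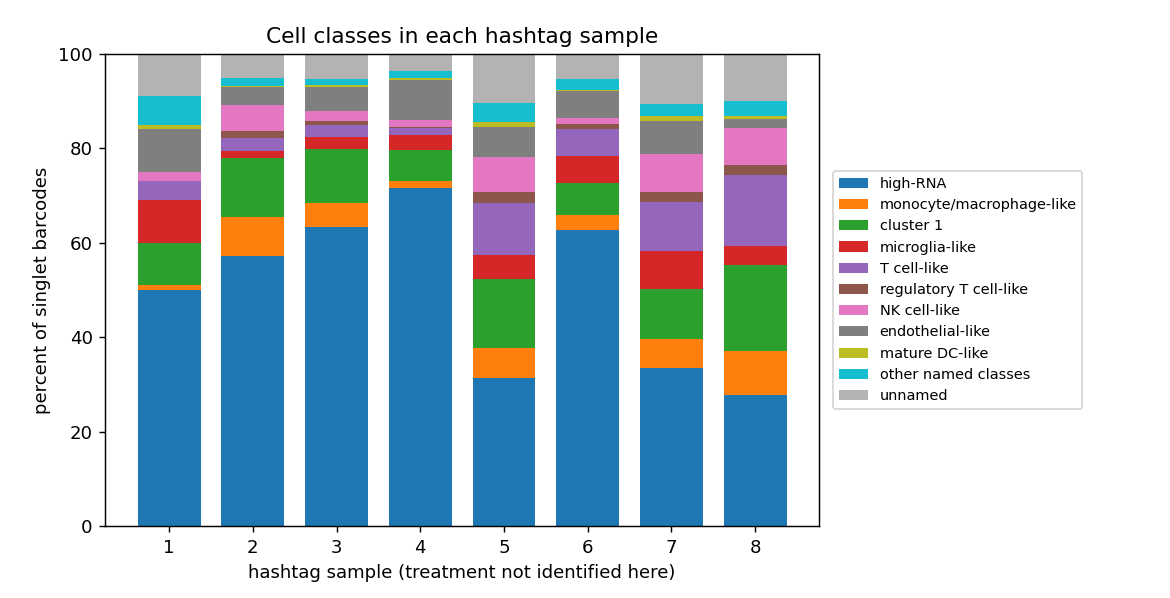
Share of each cell class among singlet barcodes, in percent, as stacked bars for the 8 hashtag samples, whose treatment is not identified here. High-RNA barcodes range from 27.8% in sample 8 to 71.6% in sample 4, and cluster 1, an unnamed macrophage cluster, from 6.64 to 18.2%.

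The series title names Cxcl10, a chemokine that attracts cells bearing the receptor Cxcr3, and the treatment antibodies bind the products of Vsir (VISTA) and Cd274 (PD-L1). Where these 3 genes were expressed was examined across the classes. Cxcl10 was most abundant in monocyte/macrophage-like cells, with a median of 3651 CPM (2348 to 6271 over 6 hashtag samples), against 1459 CPM in cluster 1 (328 to 1782 over 7) and 1381 CPM in microglia-like cells (753 to 2018 over 5). By the mean of per-cell CPM the microglia-like median was 708, below the value of the summed counts. Vsir had its highest median in microglia-like cells, at 355 CPM (185 to 480.2), against 131 CPM (123 to 142) in monocyte/macrophage-like cells and 133 CPM (121 to 195) in cluster 1. Cd274 stood at 468 CPM in mature dendritic cell-like cells, which reached 20 cells in sample 5 only. It was at 145 CPM (58.2 to 201) in cluster 1, 119 CPM (77.4 to 226) in monocyte/macrophage-like cells and 63.4 CPM (40.7 to 117) in microglia-like cells.

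Lower levels were found in most other classes. Median Cxcl10 was 497 CPM in regulatory T cell-like cells, 419.6 CPM in NK cell-like cells, 305 CPM in T cell-like cells, 193 CPM in endothelial-like cells and 289 CPM in the mature dendritic cell-like cells of sample 5. Neutrophil-like cells reached 20 cells in 1 sample only, where Cxcl10 stood at 2839 CPM, Cd274 at 193 CPM and Vsir at 132 CPM. Vsir was at 70.9 CPM in regulatory T cell-like cells, 68.5 CPM in T cell-like cells and 29.9 CPM in NK cell-like cells. Cd274 was at 86.8, 61.6 and 58.1 CPM in those 3 classes. High-RNA barcodes held the genes at medians of 18.0, 7.40 and 1.95 CPM for Cxcl10, Vsir and Cd274. Cxcl10 in cluster 1 of sample 4, from 33 cells, lay far below the other samples (1283 to 1782 CPM without it).

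In the GRCm38.p6 annotation, the build named mm10 in the processing notes, Cxcl10 (ENSMUSG00000034855) spans 92346638 to 92348889 on chromosome 5. Vsir (ENSMUSG00000020101) spans 60346851 to 60430294 on chromosome 10, and Cd274 (ENSMUSG00000016496) spans 29362107 to 29388095 on chromosome 19. All 3 are annotated as protein-coding, and the counts are 3' tags summed over each gene.

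The share of cells with a UMI was compared after thinning each cell to 2000 UMIs, which left out 1 microglia-like and no monocyte/macrophage-like cell. A Vsir UMI was then seen in a median of 56.7% of microglia-like cells and 21.8% of monocyte/macrophage-like cells (96.6 and 64.3% without thinning). A Cxcl10 UMI was seen in 30.0% and 66.8% (50 and 81.8% without thinning), and a Cd274 UMI in 8.96% and 18.1% (30.8 and 45.9% without thinning). The monocyte/macrophage-like medians include sample 2, which had too few microglia-like cells. In sample 3 the Vsir shares were close, at 26.7% of microglia-like and 22.6% of monocyte/macrophage-like cells. They were 56.7 to 67.8% and 18.6 to 26.2% in samples 5 to 8. Cluster 1 gave thinned shares of 23.7, 43.7 and 23.4% for Vsir, Cxcl10 and Cd274. High-RNA barcodes, with a median depth of 80716.5 UMIs against 8754 and 9450.75, gave 1.76, 2.72 and 0.406%, or 42.5, 44.3 and 11.6% without thinning. Thinned shares of Vsir, Cxcl10 and Cd274 were 7.14, 6.25 and 3.39% in endothelial-like cells (median depth 8103.5 UMIs), 4.55, 18.8 and 7.11% in NK cell-like cells (4406 UMIs) and 12.97, 18.8 and 11.7% in T cell-like cells (4685 UMIs), with 22, 7 and 27 cells left out. Without thinning they were 23.1, 16.8 and 14.1%, 12.9, 28.1 and 22.0%, and 31.3, 24.8 and 25.4%. Which of these shares is the background of myeloid barcodes was not settled, and the Cd274 share of microglia-like cells lay below that of T cell-like cells.

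**Figure D2:**
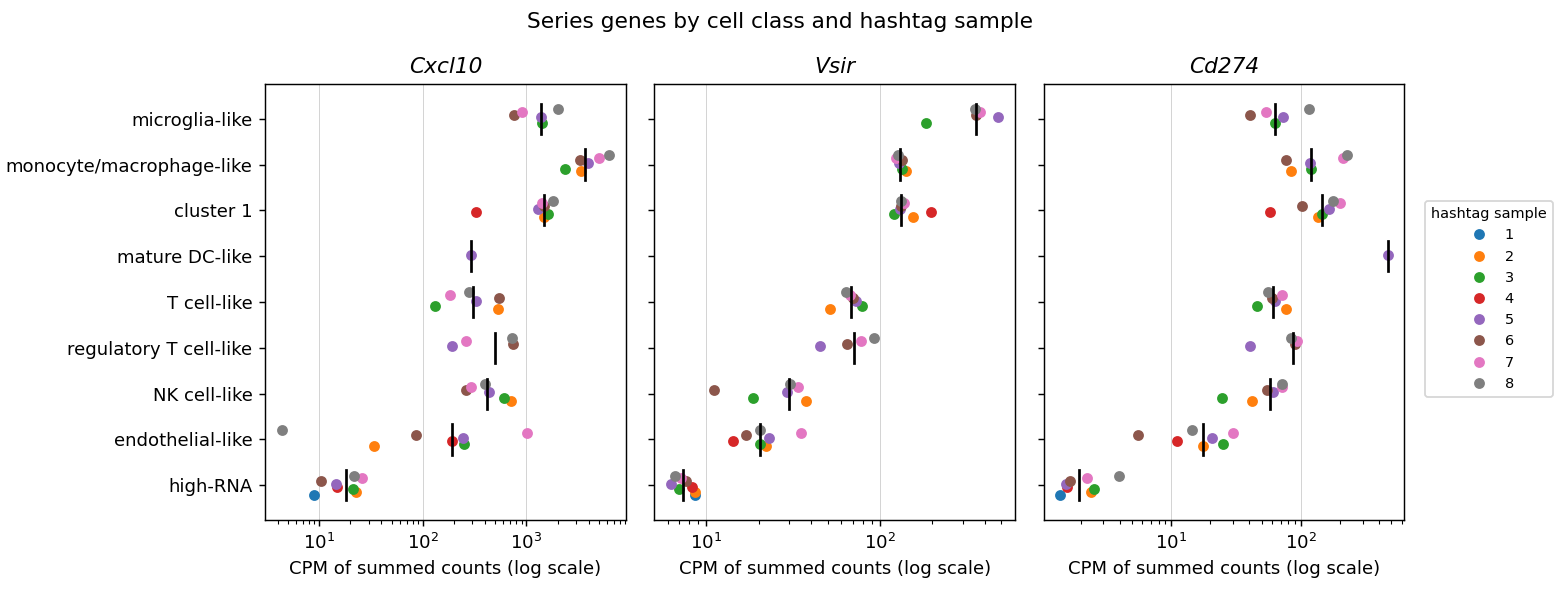
CPM of summed counts (log scale) of Cxcl10, Vsir and Cd274 in the main cell classes and in cluster 1, with a point per hashtag sample of at least 20 cells and a bar at the median. Cxcl10 has medians of 3651 in monocyte/macrophage-like and 1381 in microglia-like cells, Vsir has its highest median in microglia-like cells at 355, and Cd274 reaches 468 in mature dendritic cell-like cells, whose Vsir count of 0 cannot be drawn on a log axis.

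The microglia-like and monocyte/macrophage-like classes were named by marker genes, and the origin of their cells was not tested. They were compared within the 5 hashtag samples (3, 5, 6, 7 and 8) that held at least 20 cells of both classes, with 30 to 120 microglia-like and 62 to 161 monocyte/macrophage-like cells each. Fold changes are microglia-like over monocyte/macrophage-like, and a gene that rose was higher in microglia-like cells. Microglia-like cells were lower in most interferon-stimulated, inflammatory cytokine, glycolysis and antigen presentation genes, and higher in all measured homeostatic microglia and cell cycle genes and most immediate early genes. Of these lists only cell cycle kept its call with an estimated correlation (adjusted p = 0.0218, against adjusted p from 0.259 to 0.5685 for the others). The correlation of its 15 genes was estimated at -0.025, against 0.23 to 0.76 for the others. Between the T cell sides the same genes gave 0.87, so the kept call rests on an estimate that was not stable between comparisons. Vsir rose (log2 fold change 1.12, SE 0.16, edgeR adjusted p = 5.17e-05), with means of 323 and 145 CPM. Cd274 fell (-1.38, SE 0.18, adjusted p = 1.83e-05, 64.4 against 171 CPM) and Cxcl10 fell (-1.98, SE 0.21, adjusted p = 3.58e-06, 1200.3 against 4721 CPM), each in 5 of 5 samples. Cxcl10 is a leading gene of the monocyte/macrophage-like cluster. It changed by -1.97 (SE 0.18) with clusters drawn without the list genes, by -0.54 (SE 0.13, adjusted p = 0.00433) with classes from antibody tag clusters, and by -0.48 (SE 0.15, adjusted p = 0.0205) against cluster 1.

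Of 7268 genes that are no cell type marker, 4249 passed the edgeR test, 2229 higher and 2020 lower in microglia-like cells. Of the largest increases outside the lists, Rtn4rl1, Sgce, Tpbgl and Tgfa had no UMI in monocyte/macrophage-like cells. Against a floor of 3 counts over that class they were at least 81.8-fold, 65.5-fold, 53.6-fold and 45.1-fold higher. Lrrc3 had 1 UMI there, and its ratio of summed CPM was 414 with an exact 95% counting interval of 73.9 to 16404.1. The largest decreases were in Inhba (log2 -6.20, SE 0.39), which encodes a subunit of activin, the growth factor gene Nrg1 (-5.00, SE 0.32), Dmkn (-4.84, SE 0.23), the integrin gene Itga1 (-4.75, SE 0.50) and the myeloid protease gene Prtn3 (-4.66, SE 0.45). Inhba changed by -2.25 under the hashtag margin rule, and Itga1 by -2.30 with classes from antibody tag clusters.

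Of 26 interferon-stimulated genes 24 fell, or 25 adjusted over the list alone (median log2 -1.73, camera adjusted p = 5.02e-11, adjusted p = 0.339 with an estimated correlation). Gbp2, a guanylate-binding protein, fell by 2.82 (SE 0.22) and the antiviral gene Rsad2 by 2.76 (SE 0.32) on the log2 scale, and Ifit1, Isg15 and Irf7 changed by -2.75, -2.11 and -1.57. Of 17 antigen presentation genes 13 fell, and adjusted over the list alone 13 fell and 1 rose (median -0.83, camera adjusted p = 0.0120, adjusted p = 0.5685 with an estimated correlation). The list median was 0.10 in sample 3 and -1.22 to -0.47 in the other samples. The MHC class II chaperone Cd74 changed by -1.24 (SE 0.26), the peptide transporter Tap1 by -1.14 (SE 0.13) and H2-Ab1 by -0.94 (SE 0.31, lower in 3 of 5 samples). Cd74 changed by -4.67 with classes from antibody tag clusters and by -2.43 against cluster 1. The antibody tag I-A-I-E, which binds MHC class II on the surface, went the other way, with a median log2 ratio of 1.15 by share (-0.051 to 2.32, higher in 4 of 5 samples, exact sign-flip adjusted p = 0.143) and 308 against 220.5 tags per cell, but -0.42 with cluster 1 added. The class I genes H2-K1 (-0.022) and B2m (-0.031) did not pass. Against cluster 1, which MHC class II genes lead, all 17 fell.

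Chemokines split, with 7 of 14 falling and 4 rising (median log2 -0.45, camera adjusted p = 0.390). Their median was 0.40 in sample 3 and -1.80 to -0.35 in the other samples, and -1.57 with cluster 1 added to the class, -1.29 against it alone, and -1.37 and -1.31 with Leiden seeds 1 and 3. The neutrophil attractant Cxcl1 fell (-3.31, SE 0.56, in 4 of 5 samples), whereas Ccl12 (3.85, SE 0.22), Ccl3 (1.92) and Ccl4 (0.92) rose. Cxcl2 fell (-2.90, SE 0.28), leads the monocyte/macrophage-like cluster, and changed by -2.84 with clusters drawn without the list genes. Of 9 inflammatory cytokines 7 fell and 2 rose (median -1.90, camera adjusted p = 1.23e-04, adjusted p = 0.259 with an estimated correlation). Cxcl3 (-6.03, SE 0.29) and Il6 (-3.92, SE 0.17) fell and Tnf (1.30, SE 0.14) rose, while Il1b and Il1a are leading genes of the compared clusters. Against cluster 1 only 2 cytokines fell and 3 rose (median -0.198), and Il6 did not pass (-0.52). The list median was -0.87 with cluster 1 added to the class, -0.44 with classes from antibody tag clusters, and -0.93, -0.95 and -1.26 with Leiden seeds 1, 3 and 4.

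Of 15 measured myeloid checkpoint and suppression genes, 9 fell and 3 rose (median log2 -0.75, camera adjusted p = 0.0156, adjusted p = 0.339 with an estimated correlation). The prostaglandin synthase gene Ptgs2 (-3.19, SE 0.23) and Il10 (-2.84, SE 0.42) fell, and Vsir, Sirpa (0.78) and Entpd1 (0.55) rose. The list median was -1.29 without sample 3 and -0.23 with classes from antibody tag clusters. Of 4 measured T cell checkpoint genes, of which Vsir, Havcr2 and Entpd1 are in the myeloid checkpoint list as well, 3 rose (median 0.84, camera adjusted p = 0.0156, adjusted p = 0.339 with an estimated correlation). One of them, Lag3, an inhibitory receptor, stood at 87.6 CPM in microglia-like and 1.37 CPM in monocyte/macrophage-like cells (log2 6.06, SE 0.35, adjusted p = 1.73e-08). The median of these 4 was 1.68 with classes from antibody tag clusters and 0.44 against cluster 1. Of 2 measured cytotoxicity genes, Tnf rose and Ccl5 (-0.60, SE 0.12) fell (median 0.35, camera adjusted p = 0.637). The list median was 0.84 without sample 3, 0.97 without sample 5, 0.92 without sample 7, -0.64 with classes from antibody tag clusters, 1.504 under the hashtag margin rule, 1.09 with no filter on low counts and 0.12 at doubled resolution. It was 1.41 against cluster 1, 1.36 with cluster 1 added, 0.078 without barcodes over 30000 UMIs and 0.037 to 1.33 over the Leiden seeds. Ccl5 did not pass without the block (-0.54) and stood at 3.3e-04 under the hashtag margin rule, but at -0.95 with clusters drawn without the list genes, -3.70 (SE 0.55, adjusted p = 1.78e-04) with classes from antibody tag clusters and -2.13 against cluster 1.

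All 14 homeostatic microglia genes not used for naming rose (median log2 3.25, camera adjusted p = 2.69e-16, adjusted p = 0.259 with an estimated correlation), among them the adhesion receptor gene Adgrg1 (6.15, SE 0.29). The fructose transporter gene Slc2a5 had 2 UMIs in monocyte/macrophage-like cells, with a ratio of summed CPM of 229 (exact 95% counting interval 62.9 to 1892.9). This list includes Cx3cr1, a leading gene of the microglia-like cluster, and 13 rose with clusters drawn without the list genes (median 3.15). Of 17 disease-associated microglia genes, described in microglia around amyloid and injury, 8 rose and 3 fell (median 0.40, camera adjusted p = 0.00321, adjusted p = 0.339 with an estimated correlation). Trem2 (3.09, SE 0.14), Cst7 (3.02, SE 0.28), Ctsd (2.92) and Cd9 (2.49) rose, while Apoe (-0.026) and Spp1 (-0.21) did not pass. The list median was -0.35 in sample 7, 0.26 without sample 3, and below 0 with 5 of 10 Leiden seeds (-0.61 to -0.027). Against cluster 1, 6 of 18 rose and 11 fell (median -0.58), and with cluster 1 added to the class 7 rose and 10 fell (median -0.52).

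All 15 cell cycle genes rose (median log2 2.77, camera adjusted p = 3.62e-11, adjusted p = 0.0218 with an estimated correlation), including Stmn1 (3.98, SE 0.18) and Mki67 (3.23, SE 0.30), expressed in dividing cells. The median was 0.95 with classes from antibody tag clusters, 1.46 against cluster 1 and 1.56 to 1.70 with Leiden seeds 1, 3 and 4. At 2000 UMIs per cell, at least 3 UMIs of these genes were found in 10.4 to 26.7% of microglia-like and at most 1.61% of monocyte/macrophage-like cells per sample (33.3 to 76.7% and 6.45 to 17.1% without thinning). High-RNA barcodes gave 36 to 59.1% after thinning, endothelial-like cells 4.05 to 21.7%, T cell-like cells 0 to 16.7% and NK cell-like cells 2.17 to 7.69%, so the shares of microglia-like cells overlapped those of endothelial-like and T cell-like cells. Of 11 glycolysis and hypoxia genes, 9 fell and 1 rose (median -0.96, camera adjusted p = 0.00437, adjusted p = 0.339 with an estimated correlation). Vegfa (-2.65, SE 0.27), Slc2a1 (-1.67, SE 0.14) and Pgk1 (-1.39) fell and Hk2 (0.45) rose. Immediate early genes, which tissue dissociation can induce, rose in 8 of 14 cases and fell in 3 (median 0.75, camera adjusted p = 0.00437, adjusted p = 0.339 with an estimated correlation). Jun (2.89, SE 0.15), Fosb (2.17, SE 0.14) and Egr1 (1.95) rose together with the lists above, and the list median was 1.504 with classes from antibody tag clusters.

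Markers of other cell types were measured in the same sums. Of 4 border-associated macrophage markers 1 fell (median log2 0.018), and all 4 patrolling monocyte markers (-2.35) and 3 of 4 neutrophil markers (-2.62) fell. Of type 1 dendritic cell markers 2 of 4 rose and 1 fell, and 1 of 3 type 2 dendritic cell markers fell, or 2 adjusted over the list alone. Both mature dendritic cell markers and all 3 plasmacytoid dendritic cell markers rose, Siglech among the latter, which microglia also express. Both B cell markers rose and both plasma cell markers fell. The only astrocyte marker rose, the only type 2 innate lymphoid marker, Areg, fell, oligodendrocyte markers split 1 up and 1 down, and 1 of 2 endothelial markers fell. The single T cell, regulatory T cell and choroid plexus markers and the only measured carcinoma marker, Krt8 (-0.31), did not pass. Adjusted over the list alone, the counts of the 10 gene lists other than interferon-stimulated and antigen presentation were the same as over all genes. The count of passing genes stayed between 3229 and 5459 under every alternative tried, and 5034 passed with cluster 1 added to the class. Several named genes kept their direction and call but moved by over 1.5 times. Against cluster 1, Ptgs2 changed by -1.58, Gbp2 by -1.81, Rsad2 by -1.76, Cxcl2 by -1.63, Vegfa by -1.56, Slc2a1 by -0.79, Dmkn by -1.32, Ccl12 by 1.68, Trem2 by 1.59 and Stmn1 by 2.01. With classes from antibody tag clusters, Vsir changed by 1.87, Cst7 by 1.48, Tnf by 2.43, Stmn1 by 1.89, Il6 by -1.82 and Nrg1 by -7.99. Cxcl3 changed by -3.76 under the hashtag margin rule, Vegfa by -4.00 without barcodes over 30000 UMIs, and Lag3 by 4.04 with Leiden seed 4.

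**Figure D3:**
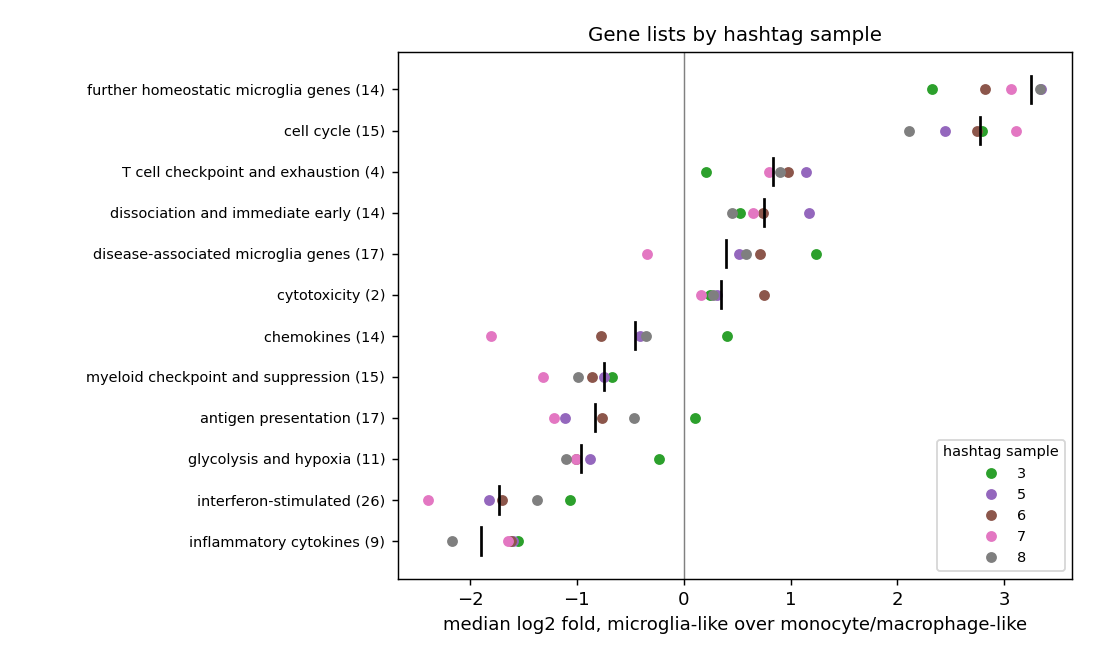
Median log2 fold change of each gene list, microglia-like over monocyte/macrophage-like, with the number of measured genes in brackets, a point per hashtag sample and a bar for the median from the fit over 5 samples. Interferon-stimulated genes lie below 0 and cell cycle genes above 0 in all 5 samples, with medians of -1.73 and 2.77.

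The antibody tags measured the surface proteins of the same classes. As a share of all antibody tags, 19 of 32 antibodies were higher and 4 lower in microglia-like cells in all 5 samples, 23 in all. Chance gives 2 for independent antibodies, but shares sum to a fixed total. A fall of abundant tags such as CD45 and Ly6C raises the shares of others, so no conclusion is drawn from 23 against 2. CD64, an Fc receptor, had a median log2 ratio of 1.74 (1.67 to 2.32), the macrophage protein F4/80 1.41 (0.71 to 1.53, but 13.1 against 14.3 tags per cell), CD11c 1.34 (0.88 to 2.42), CD172a 1.27 and Siglec-H 1.18. CX3CR1, the fractalkine receptor of microglia, had 1.82 (-1.39 to 2.57, higher in 4 of 5 samples). The exception was sample 5, where monocyte/macrophage-like cells held 255.7 CX3CR1 tags per cell, or 6.80% of their tags, against 14.5 to 24.2 tags per cell in the other samples. The microglial protein TMEM119 had 0.66 by share, with 2.07 against 2.52 tags per cell. CD49d had -0.74 (-0.96 to -0.47), Ly6C, a marker of inflammatory monocytes, -0.67 (-1.05 to -0.25, 284 against 871 tags per cell), CD44, an adhesion receptor of infiltrating leukocytes, -0.67 (53.2 against 179.7 tags per cell) and CD45 -0.28 (28.6 against 40.8% of tags). The PD-L1 tag had 0.51 by share (-0.062 to 1.33, higher in 4 of 5 samples), but a lower median of 9.97 against 14.4 tags per cell. It had -0.39 with cluster 1 added to the monocyte/macrophage-like class, when 9 of the 32 antibodies turned sign. I-A-I-E, which binds MHC class II, then stood at -0.42, CD86 at -0.32, Ly6G at 1.07 (from -0.030), CD4 at 0.47, CD11c at -0.065, CD38 at -0.0099, Ly6C at 0.025 and CD24 at 0.075. Without barcodes over 30000 UMIs, the Ly6C median was -0.093 and the TMEM119 median 1.24.

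No antibody passed, since an exact two-sided sign-flip test over 5 samples cannot give a p under 0.0625, and none had an unadjusted p under 0.05 by share or by centred log ratio. The smallest adjusted p was 0.0870 by share and 0.118 by centred log ratio. By centred log ratio 9 antibodies were higher and 8 lower in all 5 samples, and the median of 5 antibodies turned sign, PD-L1 (-0.087) among them. Those with 1 direction in all samples under both scalings were CD117, CD11c, CD172a, CD38, CD45R-B220, F4/80, CD103, CD64 and CD83 (higher) and CD44, CD45, Ly6C and CD49d (lower). In tags per cell the median was lower in microglia-like cells for 22 of 32 antibodies, F4/80, CD38, CD45R-B220 and CD103 among them. In sums of at least 10 cells, a limit chosen after the data were seen, 6 samples entered and 23 antibodies passed the exact test (19 higher, 4 lower, smallest adjusted p 0.0435). With the planned hashtag margin rule 6 samples entered as well, 14 antibodies were higher and 5 lower in all of them, and 0 passed the exact test (19 at an unadjusted p under 0.05, smallest adjusted p 0.0526).

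T cells were then compared by side of the CD8 and CD4 antibody tags, in hashtag samples 5, 6, 7 and 8. Of 979 T cell-like and regulatory T cell-like singlets, 613 fell on the CD8 side, 354 on the CD4 side and 12 between. The CD8 side reached down to a log2 ratio of CD8a to CD4 tags of -3.22, where CD4 tags outnumber CD8a tags. Other lymphocytes were not separated from CD8 T cells on that side. In the 4 samples compared, regulatory T cell-like cells, a cluster named by its marker genes, made up 130 of 321 cells (40.5%) on the CD4 side and 9 of 561 (1.60%) on the CD8 side. Cytotoxicity genes and the chemokines Ccl3 and Ccl4 were higher on the CD8 side. All 9 measured cytotoxicity genes rose on the CD8 side (median log2 2.25, camera adjusted p = 1.35e-36, adjusted p = 0.0155 with an estimated correlation), among them the pore-forming protein gene Prf1 (3.87, SE 0.31), Gzma (2.92, SE 0.49) and Ifng (2.75). Gzma did not pass without the block (2.14), and in the T cell-like cluster alone 7 of 9 measured there rose (median 1.65). Neither Cxcl10 (-0.198, SE 0.16, edgeR adjusted p = 0.678), Vsir (-0.10, SE 0.22, adjusted p = 0.921) nor Cd274 (-0.59, SE 0.23, adjusted p = 0.226) passed.

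Of 5511 genes, 286 passed, 112 higher and 174 lower on the CD8 side. Only Cd4, Cd8a and Cd8b1 were left out of this count, which includes cell type markers, among them the 5 regulatory T cell markers. Chemokines rose in 3 of 5 cases and fell in 1 (median log2 2.89, camera adjusted p = 5.05e-10, adjusted p = 0.0419 with an estimated correlation), with Ccl3 at 3.97 (SE 0.45), Ccl4 at 3.44 (SE 0.17) and Cxcl2 at -0.93. That correlation was estimated at -0.21 over these 5 genes. T cell checkpoint genes split, with 3 of 12 rising and 5 falling (median -0.025, mean -0.26, camera adjusted p = 1.56e-04, adjusted p = 0.0945 with an estimated correlation). Cd160 (4.33, SE 0.40), Havcr2 (1.49, SE 0.38) and Lag3 (1.10) rose, and Tnfrsf4 (-4.53, SE 0.30), Tnfrsf18 (-2.31), Ctla4 (-1.65) and Icos (-1.15) fell. Interferon-stimulated genes fell in 7 of 25 cases (8 adjusted over the list alone, median -0.41, camera adjusted p = 1.73e-06, adjusted p = 0.424 with an estimated correlation), among them Iigp1 (-2.11, SE 0.31) and Ifi27l2a (-1.07, SE 0.13), lower in all 4 samples, and Ifi204 (-1.28, lower in 3 of 4). The list median was 0.14 in sample 6 and -0.96 to -0.41 in the other samples. The chemokine median was 1.16 without sample 6, 1.65 without sample 7, 0.34 with no filter on low counts and 1.84 in the T cell-like cluster alone, the T cell checkpoint median -0.21 without sample 7 and 0.088 without sample 8, and the interferon-stimulated median -0.63 without sample 6 and -0.14 without sample 8.

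Few genes of the remaining lists passed between the sides. None of 15 cell cycle genes (camera adjusted p = 0.4927) and none of 14 antigen presentation genes (camera adjusted p = 0.638) passed in edgeR, where 1 and 3 had an unadjusted p under 0.05, and none passed in DESeq2. Of 9 myeloid checkpoint genes Havcr2 rose and Nt5e (-1.14, SE 0.21) fell (camera adjusted p = 0.791). Of 10 disease-associated microglia genes 3 rose, with 1 more falling when adjusted over the list alone (camera adjusted p = 0.4927), including Tyrobp (1.58, SE 0.37) and Ctsd (0.84, SE 0.15). Of 6 homeostatic microglia genes Cx3cr1 (1.49, SE 0.29) and Selplg (0.64, SE 0.16) rose, with 1 falling when adjusted over the list alone (camera adjusted p = 0.159). Pkm (-0.78, SE 0.15) fell among 8 glycolysis genes (camera adjusted p = 0.0613). Nfkbia (-1.14, SE 0.13) and Nfkbiz (-0.89, SE 0.199) fell among 12 immediate early genes, or 1 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.0770). The only measured inflammatory cytokine, Il1b, did not pass in edgeR (-1.19, unadjusted p 0.0244) or DESeq2, though its single p passed when adjusted over the list alone. It was lower on the CD8 side in 2 of 4 samples, with log2 ratios of -2.78, -0.61, 0.15 and 0.47 in samples 5, 6, 7 and 8.

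The largest increases outside the lists were in the NK receptor genes Klrc2 and Klrc1 (log2 4.34, SE 0.36), the chemokine Xcl1 (4.87, SE 0.46), Wdr95 and Crtam. On the CD4 side Klrc2 had 2 UMIs and Wdr95 and Crtam 3 each, with ratios of summed CPM of 85.7 (exact 95% counting interval 23.6 to 710.3), 22.7 (7.61 to 111) and 20.1 (6.73 to 98.7). The largest decreases were in Itgb8 (-4.31, SE 0.497), Penk (-4.23, SE 0.61), Bmyc (-3.63, SE 0.23), Lrrc32 (-3.55, SE 0.46) and Izumo1r (-3.26, SE 0.22). All 5 regulatory T cell markers, Ctla4 and Tnfrsf4 among them, fell, but these markers named the regulatory T cell-like cluster, so their fall is no independent result. In the T cell-like cluster alone, Tnfrsf4 (-2.84) and Ctla4 (-1.01) fell, Il2ra rose (2.18, SE 0.51, adjusted p = 0.00759), Ikzf2 did not pass (0.47) and Foxp3 was not tested, and of the 5 largest decreases only Izumo1r was tested. Along with these lists, both measured type 2 innate lymphoid markers, the only B cell marker and 1 of 2 endothelial markers fell. All 3 NK cell markers, both gamma delta T cell markers (median log2 6.18), the single neuron marker, Nrgn, and 3 of 6 monocyte/macrophage markers (camera adjusted p = 4.35e-06, adjusted p = 0.0747 with an estimated correlation) rose on the CD8 side. Klrd1 rose as well, listed as a type 2 dendritic cell marker and also expressed by NK cells. Of 9 T cell markers 1 fell, or 2 adjusted over the list alone. On the CD8 side, 72.4% of cells held a Cd8a or Cd8b1 UMI and 2.28% a Cd4 UMI, against 5.65 and 56.2% on the CD4 side. Of the CD8 side cells, 189 had CD8 tags below 4 times the CD4 tags, and 21.7% of those held a Cd8a or Cd8b1 UMI, while 73 cells lay within 1 log2 unit of a limit.

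The count of genes moved with the tool, the filter, the cells and the samples. Leaving out sample 5 gave 182 genes, the DESeq2 Wald test 183, sides drawn by RNA 186, no filter on low counts 486 and the T cell-like cluster alone 564. In that cluster alone, which reached the cell limit on both sides in samples 5, 7 and 8 only, 9 of 12 cell cycle genes rose (median log2 1.89) and 16 of 24 interferon-stimulated genes fell (-1.11), and Cd274 passed (-0.93). With CD8 tags at least 4 times the CD4 tags, Cxcl10 passed (-0.82). Havcr2 lost its call without sample 5 (1.79), 7 (1.55) or 8 (0.83), Selplg without 5 (0.68), 6 (0.55) or 7 (0.53), Pkm without 5 (-0.74) or 7 (-0.73), Nfkbiz without 6 (-0.77) or 7 (-0.74), and Tyrobp without 7 (1.13). Without sample 5, Tyrobp stood at 2.53 and the Penk log2, CD8 over CD4 side, at -6.89. With the DESeq2 Wald test Havcr2 (1.48), Tyrobp (2.01) and Cx3cr1 (1.499) lost their calls, and Tyrobp stood at 0.29 with sides drawn by RNA. In the T cell-like cluster alone, Ccl3 (6.70), Ccl4 (5.28) and Havcr2 (3.55) were larger, Gzma (1.45) and Tnfrsf4 (-2.84) smaller, and Cx3cr1 (0.96), Selplg (0.27) and Pkm (-0.20) lost their calls.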

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

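The groups of values examined in this part were chosen after the data had been seen, and no explanation is tested in it. In each of 57 groups of values over hashtag samples, the gap between an extreme sample and its nearest neighbour was set against the range. In 14 groups the extreme sample stood apart, where chance gives about 1 in 20, or 2.85.

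PD-1 tags stood apart in hashtag sample 5 in 6 cell classes. T cell-like cells of sample 5 did not stand apart (15.1 tags per cell, against 15.5 in sample 6), nor did microglia-like cells (6.42 against 5.75). In the 6 classes the gap was clear. PD-1 reached 29.4 tags per cell in regulatory T cell-like cells (11.96 to 14.7 in the other samples), 17.2 in cluster 1 (2.73 to 5.15), 10.1 in monocyte/macrophage-like cells (2.56 to 3.77), 4.62 in NK cell-like cells (1.38 to 1.81), 4.44 in endothelial-like cells (1.30 to 2) and 4.30 in high-RNA barcodes (1.94 to 2.77). PD-L1 tags reached 52.1 per cell in the 30 microglia-like cells of sample 3, against 1.43 to 14.3 in the other samples. Of those 30 cells 8 exceeded 30000 UMIs, and their median was 17216 UMIs, against 7639.5 to 10435.5 in samples 5 to 8. CX3CR1 tags, which were not among the 57 groups, reached 255.7 per cell in monocyte/macrophage-like cells of sample 5 (14.5 to 24.2 elsewhere).

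Cxcl10 stood at 328 CPM in the 33 cluster 1 cells of sample 4 (1283 to 1782 elsewhere) and at 1013 CPM in endothelial-like cells of sample 7 (4.35 to 252 elsewhere), where Vsir stood at 35.2 CPM (14.3 to 22.9 elsewhere). The mean of per-cell Cxcl10 CPM there was 354, and 14.1% of the 78 cells held a Cxcl10 UMI (8.11% after thinning). The Cd274 log2 ratio of microglia-like over monocyte/macrophage-like cells was -2.33 in sample 7 (-1.22 to -1.01 elsewhere). Cd274 stood at 3.98 CPM in the high-RNA barcodes of sample 8 (1.39 to 2.56 elsewhere). Sample 1, with 100 singlets, held 2% choroid plexus or ependyma-like cells and 3% pericyte or fibroblast-like cells.

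Signals also appeared in features that no comparison used. Their counts include hashtag doublets and negatives. High-RNA barcodes held 1767 of 1949 mCherry UMIs and 664 of 718 RFP UMIs, in 21.4% and 9.88% of their barcodes, while microglia-like barcodes held 1 UMI of each. Scaled to depth, pericyte or fibroblast-like barcodes stood higher, at 6.64 CPM of mCherry and 1.95 CPM of RFP against 3.48 and 1.31 CPM in high-RNA barcodes. These values rest on 17 mCherry and 5 RFP UMIs in pericyte or fibroblast-like barcodes, too few to settle the RFP difference. An mCherry UMI was found in 11.4% of those 105 barcodes, whose median depth was 14558 UMIs against 86227, and endothelial-like barcodes held 1.69 CPM. The human hashtag features, which match no mouse sample, gave 1083 counts in 71 mature dendritic cell-like barcodes, or 15.3 per barcode. Cluster 1 held 5.21 per barcode, monocyte/macrophage-like barcodes 1.38 and high-RNA barcodes 0.342.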

How the results depend on the processing

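Added after the data were seen were cluster 1 joined to or in place of the monocyte/macrophage-like class, the Leiden seeds, the removal of genes that free RNA could supply, the 10-cell limit for antibodies, the stricter CD8 side, the T cell-like cluster alone and the removal of barcodes over 30000 UMIs. An earlier partition under other floating-point settings had named cluster 1. Over 10 Leiden seeds, 27 to 31 clusters formed, 1.91 to 91.3% of cluster 1 took the monocyte/macrophage-like name, most of it only in seeds 1 and 3. The myeloid gene count of 4249 stayed within 3229 (DESeq2 Wald test) and 5459 (no filter on low counts), and within 3539 to 4525 when a sample was left out. Vsir stayed higher in microglia-like cells (log2 0.99 to 1.87), and Cxcl10 (-2.29 to -0.48) and Cd274 (-1.78 to -1.14) stayed lower. Of 1104 values of named myeloid genes, 1101 kept direction and side of the threshold, 2 no longer passed and 1, Ccl5 with the margin rule (0.00033), turned sign. The disease-associated microglia median turned to -0.52 with cluster 1 added, -0.58 against it alone, and -0.58, -0.098, -0.61, -0.027 and -0.14 with seeds 1, 2, 3, 5 and 9. The cause was not tested for the seeds.

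The T cell count of 286 moved to 183 with the DESeq2 Wald test, 486 with no filter, which tests more genes, 186 with sides by RNA and 564 in the T cell-like cluster alone, and ranged from 182 to 331 when a sample was left out. Otherwise the cause was not tested. Without the block for the pairing by sample, 4292 myeloid and 275 T cell genes passed, Ccl5, Gzma and Tyrobp lost their calls, and the T cell checkpoint median was 0.038. The block changed no other named call. That median was also 0.038 with the margin rule, 0.33 with sides by RNA and 0.14 on the stricter CD8 side, and ranged from -0.21 to 0.088 when a sample was left out. Cxcl10 between the T cell sides turned to 0.18 with 10 cells per sum and 0.063 in the T cell-like cluster alone, and ranged from -0.30 to 0.0061 without single samples. Vsir turned to 0.13 with sides by RNA and ranged from -0.27 to 0.12. None of these turned values passed. Of 494 values of named T cell genes, 460 kept direction and side, 27 no longer passed, 2 newly passed and 5 turned sign.

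Among the 32 antibodies, 9 turned sign with cluster 1 added, CD11c (-0.065), CD38 (-0.0099), Ly6C (0.025), PD-L1 (-0.39), I-A-I-E (-0.42), CD86 (-0.32), CD4 (0.47), CD24 (0.075) and Ly6G (1.07). With the centred log ratio 5 did, PD-L1 (-0.087), CD11b (-0.34), CD3 (-0.18), CD86 (-0.25) and CD90.1 (-0.24). CD4 also turned to 0.053 with 10 or 50 cells per sum, 0.73 with the margin rule and 0.54 without barcodes over 30000 UMIs, CD24 to 0.0017 with 50 cells and 0.24 without those barcodes, and Ly6G to 0.070 with 10 cells. Without single samples CD4 ranged from -0.31 to 0.053, CD24 from -0.058 to 0.0017 and Ly6G from -0.46 to 0.070. The cause was not tested. The mean of per-cell CPM gave medians of 708 for Cxcl10 and 503 for Vsir in microglia-like cells. Without thinning, shares with a UMI were 50 and 81.8% for Cxcl10, 96.6 and 64.3% for Vsir and 30.8 and 45.9% for Cd274 in microglia-like and monocyte/macrophage-like cells, since deeper cells show more genes. With the stricter cell filter, the hashtag margin rule or Scrublet doublets removed, the median shares of all cell classes moved by less than the standard deviation between samples. Shares were not computed again under other clusterings. There the monocyte/macrophage-like class grew from 659 to 1919 and 1927 barcodes with Leiden seeds 1 and 3. Sums of under 50 cells, as in sample 3, limit the precision of the microglia-like values. Treated against untreated was not run.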

Other observations

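The tests of explanations below were all chosen after the results had been seen, and the genes in the next paragraphs were chosen after their values had been seen. The receptor of Cxcl10 and its inducer were found in lymphocytes. Cxcr3 had medians of 131 CPM in T cell-like, 141 CPM in regulatory T cell-like and 29.97 CPM in NK cell-like cells, against 0.244 CPM in monocyte/macrophage-like cells. Ifng, which induces Cxcl9 and Cxcl10, stood at 187 CPM in T cell-like and 163 CPM in NK cell-like cells. Cxcl9, the other main Cxcr3 ligand, had medians of 393 CPM (124 to 1361) in monocyte/macrophage-like cells, 300.5 CPM (62.4 to 2418) in cluster 1, of which it is a leading gene, and 159.8 CPM in microglia-like cells. Xcl1, which attracts cross-presenting dendritic cells, stood at 1571 CPM in NK cell-like and 471 CPM in T cell-like cells, and Cxcl12 at 392 CPM in endothelial-like cells.

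Checkpoint genes were spread over several classes. Ctla4 had a median of 1033 CPM in regulatory T cell-like cells and 215 CPM in T cell-like cells, and Pdcd1 had 195.5 and 171 CPM in T cell-like and regulatory T cell-like cells. Lag3 had 115.5 CPM (42.7 to 126) in microglia-like cells, 83.8 CPM in T cell-like cells and 0.802 CPM in monocyte/macrophage-like cells, and 265 CPM in the 23 plasmacytoid dendritic cell-like cells of 1 sample. H2-Ab1, a leading gene of cluster 1, stood there at 2922 CPM, against 1028 CPM in monocyte/macrophage-like and 896 CPM in microglia-like cells. Among high-RNA barcodes, cluster 13, led by the interferon-stimulated genes Ifit1, Ifi44 and Rsad2, had medians of 63.4 CPM for Cxcl10, 9.004 CPM for Cd274 and 1161 CPM for B2m. The other high-RNA clusters had 13.8, 1.41 and 827 CPM for these genes. H2-K1 was at 249 CPM in those other clusters and at 2939 CPM in T cell-like cells.

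Cell cycle genes were higher in microglia-like than in monocyte/macrophage-like cells, with summed CPM of 1029 and 121. RNA of the high-RNA clusters (summed CPM 1549.8) could have supplied part of this. Rhox5 and Krt8, abundant in those clusters, stood in microglia-like sums at 2.76% and 3.65% of their level there, and at the first share that RNA gives 4.71% of the excess. Without barcodes over 30000 UMIs the list median was 3.17, which argues against those barcodes as the whole source. Doublets under that limit were not weighed. At doubled resolution a microglia-like cluster with a median of 20160 UMIs held 26.6% hashtag doublets, which were left out. Doublets within a hashtag sample cannot be seen by hashtags and may remain. A difference in the number of dividing cells between the classes may remain, and no biological explanation was tested.

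Interferon-stimulated genes were lower in microglia-like cells in all 5 samples. Their median log2 fold change stayed at -1.75 with DESeq2 size factors, at -1.78 with clusters drawn without the list genes and at -1.25 with classes from antibody tag clusters. The value for size factors argues against library scaling as the whole source. Clusters without the list genes show that these genes were not needed to draw the classes. Genes that vary along with them were kept, and the monocyte/macrophage-like class was still led by Chil3, Thbs1, Hp and Lyz2. That value therefore cannot tell whether the classes were drawn by their interferon response. The antibody tag classes were named by RNA markers and held other cells, with 570 against 161 monocyte/macrophage-like cells in sample 8. They therefore cannot tell whether drawing classes from RNA is a source. A weaker interferon response of microglia and a different place in the tissue may each remain as hypotheses, and neither was tested.

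PD-L1 tags were few in hashtag sample 7, noticed by eye, and in some classes in other samples too. In monocyte/macrophage-like cells they stood at 8.86, 16, 14.4, 15.9, 3.96 and 12.6 per cell in samples 2, 3, 5, 6, 7 and 8, and in sample 7 they were 0.276 times the median of the other samples there, 0.189 times in cluster 1, 0.137 times in NK cell-like, 0.154 times in T cell-like, 0.118 times in microglia-like and 0.094 times in endothelial-like cells. Sample 8 stood near it in endothelial-like cells (2.44 against 2.13 per cell, with 6.50 to 41.5 elsewhere), and low values were also found in NK cell-like cells of sample 8 (3.34 against 1.62) and in T cell-like cells of samples 6 and 8 (2.94 and 2.90 against 1.08). The other 31 antibodies had a median ratio of 1.00 in the monocyte/macrophage-like cells of that sample (0.428 to 4.30), which argues against weaker staining of the whole sample, and Cd274 transcripts in those cells stood at 1.80 times the other samples (0.795 times in microglia-like cells), which argues against less transcript as the source. Staining with this antibody alone or access to its epitope may have differed, neither was tested, and the treatment of this sample is not identified here.

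Class labels were also swapped within samples. The 5 samples of the myeloid comparison allow 16 such splits, 1 of which, the real one, gave 4249 genes, and the highest of the others gave 0. The 4 samples of the T cell comparison allow 8, 1 of which gave 286 genes, with 0 as the highest of the others. Both numbers of splits are too few for a share under 0.05. The myeloid classes were also drawn from the same RNA, so a swapped sample turns their built-in difference into spread within the fit. The 0 of the other myeloid splits was therefore set by the design, and no conclusion about chance is drawn from it.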
